A study of Mus musculus with 6 samples.

How the data were processed

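Poly(A)-selected RNA from cultured mouse chondrocytes was sequenced as paired-end libraries. The 6 libraries form 2 groups of 3: chondrocytes given interleukin-1 beta (IL-1β) and vehicle, and chondrocytes given IL-1β and transplanted mitochondria. The labels call all of them osteoarthritic (OA), and the series title names osteocytes as the source of the mitochondria. The labels do not say whether the 3 replicates of a group were separate animals, cultures or portions of 1 culture. P-values therefore measure only the spread between these libraries. The replicate numbers are not stated to pair the samples, and no pairing was used in the tests reported. Once each gene's group means were removed, same-number libraries correlated at 0.0371, 0.00907 and -0.0152, and the other pairs at -0.0314 to 0.0257.

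The authors supplied 1 table with 2 values per gene and library. The first is FPKM (fragments per kilobase of transcript, scaled to depth), normalised for length and depth by the authors. The second is a column of estimated counts (expected counts), deposited as whole numbers and not normalised. The submitters' notes list HISAT2 2.0, StringTie 1.3.0, Bowtie 0.12.2 and the mouse build mm8, without saying which step used which. The coordinates in the table were checked against GENCODE M21 on GRCm38: 28732 of 28812 gene identifiers were found there, and 25914 genes (90.2% of 28732) had the same start and end. All coordinates below are therefore 1-based GRCm38 positions.

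The counts are not plain tallies of reads. In 1262 genes with a single transcript the ratio of count to FPKM in each library, relative to that in vehicle replicate 1, was the same for all of them to within 0.376%, and low counts piled up at 4 (2.31 to 2.84 times the number at the neighbouring values) and at 8. Each sequenced fragment is thus taken to be worth about 4 counts. Totals per library were 63547854 to 66293786 counts, each about 4 times the number of fragments on this reading. A gene at 0 in all libraries of a group was given a floor of 3 fragments over the group, or 12 deposited counts, and its fold is stated as at least the value against that floor. The floor covers counting error in the group at 0 only. The counts of the other group are taken as observed, so these folds are not strict lower bounds.

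Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr (minimum count 10), a quasi-likelihood fit with group as the only term, a two-sided test, and Benjamini-Hochberg adjustment over all genes tested with a threshold of 0.05. Fold changes are mitochondria over vehicle on the log2 scale with their standard error (SE), and levels are CPM (counts scaled to a common library size, with TMM factors) as mean and standard deviation (SD) of 3 libraries. The SE of a gene was derived from the edgeR test, as the absolute log2 fold change over the square root of the F statistic. It is therefore not a measure separate from the p-value. The plan was to use limma on FPKM, and edgeR if the file held counts, which it did. The filter kept 17290 genes.

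A total of 32 gene lists was fixed before the data were examined. They cover cartilage matrix and chondrocyte identity, matrix-degrading enzymes, the IL-1 and NF-kB response, hypertrophy and mineralisation, fibroblastic dedifferentiation, mtDNA-encoded protein genes, nuclear OXPHOS (oxidative phosphorylation) subunits, the TCA cycle, glycolysis, fatty acid oxidation, mitochondrial biogenesis, mitochondrial dynamics and mitophagy, mitochondrial chaperones and proteases, the integrated stress response, ER chaperones, antioxidant and NRF2 targets, interferon-stimulated genes, nucleic acid sensing, apoptosis regulators, senescence and p53 targets, cell cycle, cholesterol biosynthesis, autophagy and lysosome, and the TGF-beta and BMP response. The others are markers of osteocytes, macrophages, synovial fibroblasts, endothelium, adipocytes, skeletal muscle, erythroid cells and osteoclasts. Lists were tested with camera in limma 3.58.1 (preset inter-gene correlation 0.01, two-sided, adjusted over the 32 lists), and beside it with an estimated correlation and with fry. In camera each list is compared with all other genes. With an estimated correlation, camera also uses only the few degrees of freedom left by 6 libraries, which gives larger p-values whatever the correlation. A call lost there, for lists or pathways, therefore cannot show whether correlation between genes removes it. In fry a list is tested by itself, with 1 p for a shift in a single direction and a mixed p for changes in either direction. KEGG pathways of 10 to 300 tested genes, 306 in all, were tested with camera in the same way. The share of summed FPKM in the 13 mtDNA-encoded protein genes was compared by an exact two-sided permutation test over the 20 assignments, whose smallest possible p is 0.10.

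Genes are named by a rule written before the data were examined. It takes the 10 largest changes in each direction among genes past the threshold whose groups do not overlap, leaving out unnamed loci and pseudogenes. It adds the 2 to 4 members with the smallest p in each list described, and 12 genes named whatever their p (Col2a1, Acan, Sox9, Mmp3, Mmp13, Adamts5, Il6, Nos2, Ptgs2, Col10a1, Ppargc1a and Tfam). Because most of the 10 largest changes lay at very low counts, the 10 largest in each direction at a mean of at least 10 CPM in all libraries together were added after the values had been seen.

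Fold changes followed the GC content of the genes, differently from library to library. GC offsets per library (a lowess curve with span 0.3 trained on nuclear genes with a mean log2 CPM of at least 1) were therefore added to the edgeR fit as an alternative chosen after seeing the data. So were GC and length offsets (mgcv 1.9.3), counts divided by 4, limma on FPKM, TMM without the mtDNA-encoded genes, and GC offsets without 1 library or with the replicate number as a block. Alternatives fixed before the data were examined were each library left out in turn, the replicate number as a block, DESeq2 1.42.0, DESeq2 size factors in edgeR, no count filter, other pseudocounts, filters, scalings and variance models on FPKM, and a minimum fold.

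The procedure was tested on simulated data with the depths of these libraries, each gene's mean level and the dispersion trend fitted across genes. In them 100 genes were changed at each of 2 folds. Departures of single genes from that trend were not simulated, so recovery and false calls in the real data may be worse. The edgeR fit recovered 57% of genes changed 2-fold and 76% of those changed 4-fold (16846 genes run), with 9 false calls among 16653 unchanged genes. With 1 fragment worth 4 counts it recovered 54% and 69% (16759 genes run). With a GC trend like the one seen, 193 unchanged genes were called without GC offsets and 7 with them (16834 genes run). Symbols with no entry in the table (Mepe, Ahsp and Dcstamp) and list members under the count filter were left out of the list tests.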

Results

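Gene expression was measured by poly(A) RNA sequencing in 6 libraries of mouse chondrocytes, the cells of cartilage, all treated with IL-1β, an inflammatory cytokine used to model osteoarthritis in culture. In 3 libraries the cells had received vehicle and in 3 they had received mitochondria. Vehicle libraries held 64646124, 65131847 and 64936150 deposited counts, and mitochondria libraries 66293786, 63547854 and 64407644. No library of chondrocytes without IL-1β was analysed here, so levels before IL-1β are not known from these data. The comparison asks which transcripts of inflamed chondrocytes differ once mitochondria have been transplanted.

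Chondrocytes given mitochondria had higher levels of interferon-stimulated genes, of antioxidant enzymes and of glycolytic enzymes than chondrocytes given vehicle. They had lower levels of mtDNA-encoded transcripts, of cholesterol biosynthesis genes and of proliferation genes. These 6 lists were called with a preset correlation between genes, and none was called with an estimated correlation (adjusted p = 0.059 for the interferon list and 0.40 to 0.45 for the others). The estimated correlation of the interferon list (0.0117) was close to the preset of 0.01, so correlation by itself does not explain that loss. With GC offsets the median log2 fold change of the mtDNA-encoded list was -0.46, against -1.33 without. Part or all of that list's fall may therefore be GC bias. Proliferation genes were called as a fixed list of 25. The KEGG cell cycle of 119 genes was not called (camera adjusted p = 0.15). Isg15, a ubiquitin-like protein induced by interferon, rose from 2.70 ± 0.794 to 20.4 ± 5.06 CPM (SD, n = 3 per group). Nqo1, a quinone reductase and NRF2 target, rose from 108 ± 25.9 to 393 ± 19.4 CPM, and Cyp51, a sterol demethylase, fell from 81.0 ± 17.4 to 24.7 ± 1.5 CPM. Of 17290 genes tested by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 1099 were higher and 1463 lower with mitochondria, and 14728 did not pass. A change of at least 2-fold was seen in 237 of the higher and 704 of the lower genes. The 3 values of each group did not overlap in 7045 of the genes tested (40.7%, against 10% by chance), among them 2561 of the 2562 changed genes.

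These numbers rested on particular libraries: 130 genes were higher and 316 lower without vehicle replicate 2, 132 and 310 without vehicle replicate 3, and 398 and 734 without mitochondria replicate 3. On the first principal component of log2 CPM, vehicle replicate 1 (-30.39) lay nearer the mitochondria libraries than vehicle replicates 2 and 3 (-56.75 and -56.36). Of 127 named genes that passed, 75 did not pass without vehicle replicate 2, 74 without vehicle replicate 3, 40 without mitochondria replicate 3, 24 without vehicle replicate 1, 19 without mitochondria replicate 2 and 8 without mitochondria replicate 1. With GC offsets, an alternative added after seeing the data, 1566 genes were higher and 1708 lower, and 2130 genes were called in the same direction with and without them.

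**Figure D1:**
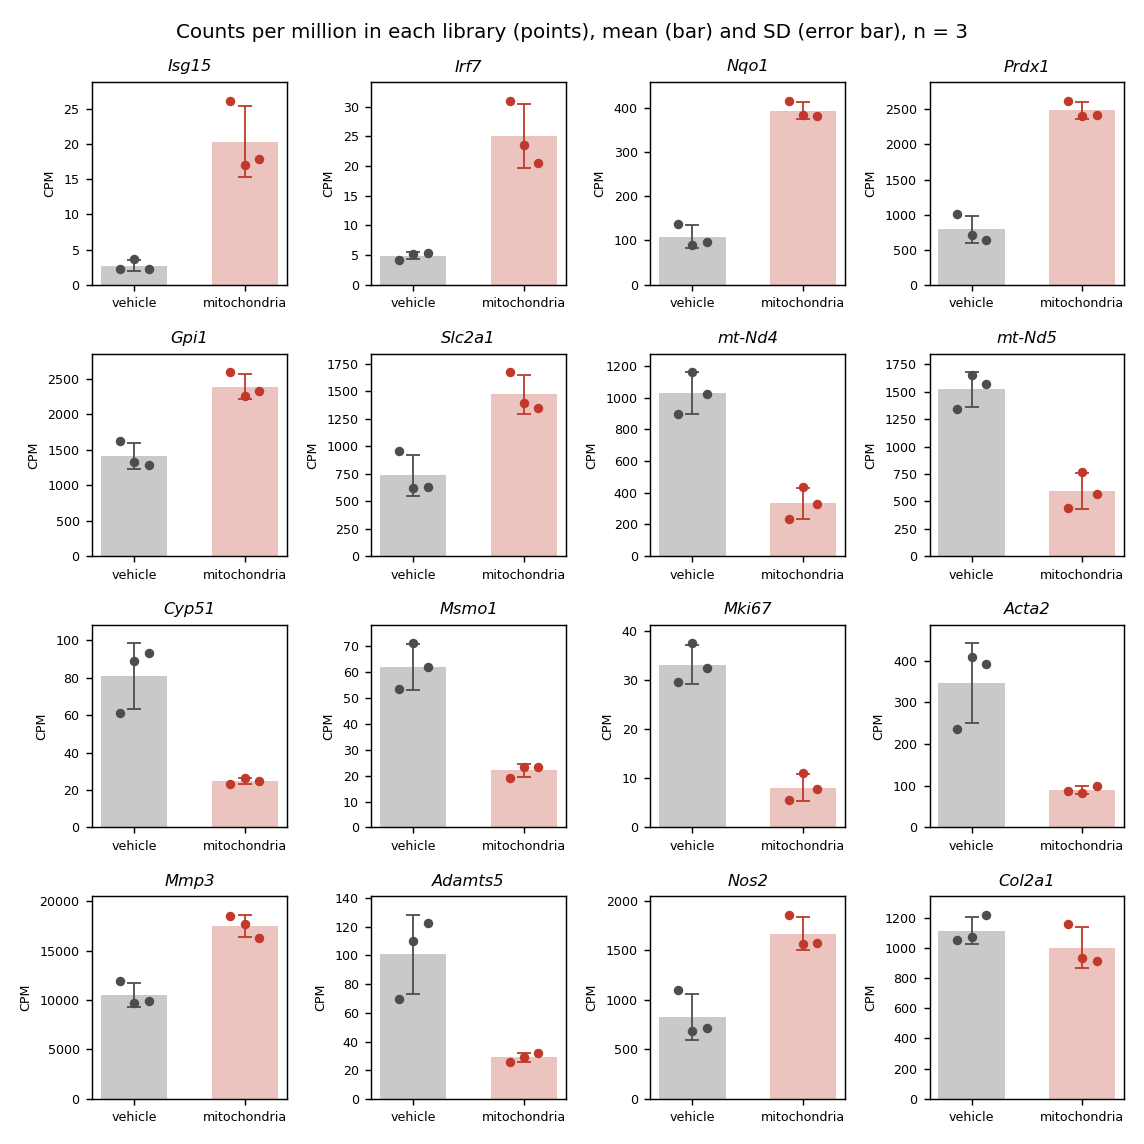
CPM (linear axes from 0) of 16 genes in each library, with points for the libraries, bars for group means and error bars for the SD (n = 3). The groups do not overlap in any gene drawn except Col2a1, whose log2 change was -0.16.

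Interferon-stimulated genes showed the largest upward shift of the lists called. Of 30 tested, 21 rose and none fell (23 rose adjusted over the list alone), with a median log2 fold change of 1.33 (camera adjusted p = 3.0e-12; adjusted p = 0.059 with an estimated correlation). Usp18, which removes Isg15 from proteins, rose by 2.99 ± 0.19 (SE; adjusted p = 0.0019, edgeR), Isg15 by 2.92 ± 0.26 (adjusted p = 0.0031), and the transcription factors Irf7 and Irf9 by 2.36 ± 0.19 and 1.34 ± 0.11 (adjusted p = 0.0029 and 0.0029). Isg15 (ENSMUSG00000035692) lies on chromosome 4 at 156199455 to 156200796, and Irf7 (ENSMUSG00000025498) on chromosome 7 at 141262706 to 141266481. The number of members that rose was 13 without vehicle replicate 2, 14 without vehicle replicate 3 and 20 without mitochondria replicate 1. Nucleic acid sensors and inflammasome genes were not called as a list: of 14 tested, 1 fell, the inflammatory caspase Casp4 (-0.92 ± 0.22, adjusted p = 0.028, edgeR), and none rose (camera adjusted p = 0.58). Casp4 failed to pass in 3 of the 6 fits with 1 library left out. Outside that list, Zbp1 (2.28, adjusted p = 0.020, edgeR) and Ddx58 (0.62, adjusted p = 0.023) rose. KEGG counts both in its cytosolic DNA-sensing pathway, where 11 of 46 genes were higher and 1 lower. Of 13 macrophage markers tested, none passed in either direction (camera adjusted p = 0.68), and their summed level was 86.4 ± 10.52 CPM with vehicle and 84.2 ± 7.37 CPM with mitochondria (SD, n = 3).

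Antioxidant and NRF2 target genes rose as a list. Of 22 tested, 15 rose and none fell (18 rose adjusted over the list alone), with a median log2 fold change of 0.79 (camera adjusted p = 2.2e-08; adjusted p = 0.40 with an estimated correlation). Nqo1 rose by 1.87 ± 0.16 (SE), the peroxiredoxins Prdx1 and Prdx6 by 1.65 ± 0.16 and 1.40 ± 0.14, and the glutathione transferase Gstm1 by 0.90 ± 0.09 (edgeR adjusted p = 0.0031 for each). Prdx1 was an abundant transcript, at 790 ± 195 CPM with vehicle and 2490 ± 120 CPM with mitochondria (SD, n = 3). Members that rose numbered 9 without vehicle replicate 2, 9 without vehicle replicate 3 and 10 without mitochondria replicate 3, against 15 with all libraries.

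Glycolysis genes rose as well. Of 21 tested, 14 rose and none fell (16 rose adjusted over the list alone), with a median log2 fold change of 0.39 (camera adjusted p = 4.8e-06; adjusted p = 0.45 with an estimated correlation). Glucose-6-phosphate isomerase Gpi1 rose by 0.76 ± 0.11 (SE; adjusted p = 0.0055, edgeR), the glucose transporter Slc2a1 from 733 ± 190 to 1470 ± 176 CPM (SD, n = 3; adjusted p = 0.0098, edgeR), phosphofructokinase Pfkp by 0.71 ± 0.13 (adjusted p = 0.012) and enolase Eno1 by 0.42 ± 0.08 (adjusted p = 0.014). With 1 library left out, 1 member passed without vehicle replicate 2, 1 without vehicle replicate 3 and 7 without mitochondria replicate 3, and camera's adjusted p stayed at or under 2.9e-05 in all 6 such fits. The median was 0.26 and Eno1 rose by 0.24 with GC offsets, and the median was 0.22 to 0.39 under the 6 rescalings tried, 4 of them in limma fits to FPKM.

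All 13 mtDNA-encoded protein genes had lower estimates with mitochondria, and 12 of them fell (12 adjusted over the list alone), with a median log2 fold change of -1.33 (camera adjusted p = 1.9e-07; adjusted p = 0.45 with an estimated correlation). These genes encode the mitochondrial genome's subunits of the respiratory chain. mt-Nd4 (MT chromosome, 10167 to 11544) changed by -1.63 ± 0.20 (SE; adjusted p = 0.0046, edgeR), mt-Nd2 by -1.37 ± 0.16 (adjusted p = 0.0042), mt-Nd5 by -1.36 ± 0.18 (adjusted p = 0.0051) and mt-Nd6 by -1.33 ± 0.18 (adjusted p = 0.0053). Their share of summed FPKM was 5.34% ± 0.582 with vehicle and 2.43% ± 0.814 with mitochondria (SD, n = 3; difference -2.91 points, exact two-sided permutation p = 0.10, the smallest this design allows). The list is rich in A and T bases, with a median GC content of 37.12%, and the median fold change was -0.46 with GC offsets, where 8 members were called and mt-Nd6 did not pass (adjusted p = 0.11, edgeR). Without vehicle replicate 2, vehicle replicate 3 or mitochondria replicate 3, 7 members were called.

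**Figure D2:**
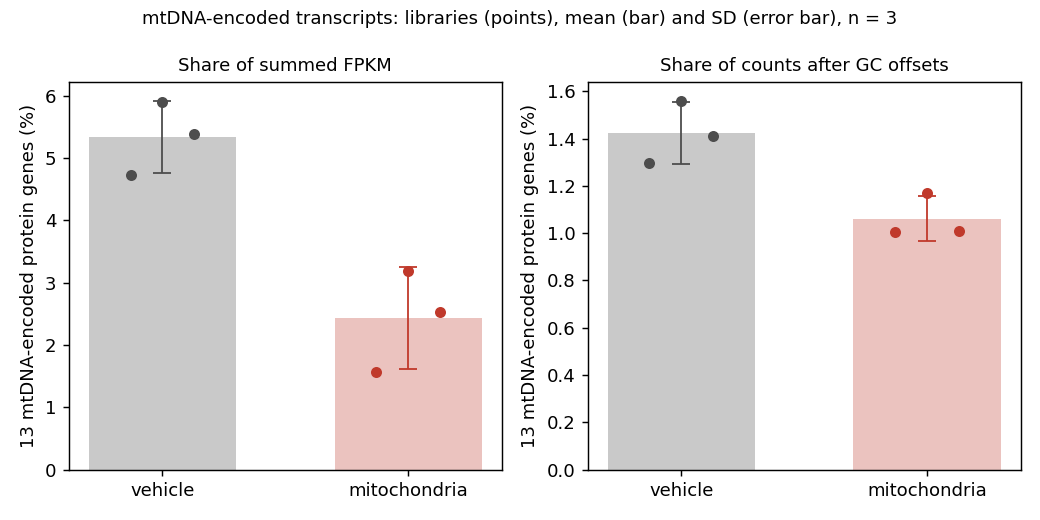
Share of the 13 mtDNA-encoded protein genes in summed FPKM (left) and in deposited counts after GC offsets (right), in percent, with points for libraries, bars for means and error bars for the SD (n = 3). Each mitochondria library lies below each vehicle library in both panels, by a mean of 2.91 points on the left.

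Nuclear genes for mitochondrial functions shifted less. Of 76 nuclear OXPHOS subunits, 6 rose and none fell (1 rose adjusted over the list alone), with a median log2 fold change of 0.18 (camera adjusted p = 3.7e-06; adjusted p = 0.62 with an estimated correlation). The complex I subunit Ndufv3 rose by 0.58 ± 0.10 (SE; adjusted p = 0.0093, edgeR) and the complex III subunit Uqcrh by 0.36 ± 0.08 (adjusted p = 0.023). The list's median was 0.03 with GC and length offsets, where the list was not called (camera adjusted p = 0.71), and no member passed without vehicle replicate 2 or without vehicle replicate 3. The TCA cycle was not called: of 18 tested, 2 fell, pyruvate carboxylase Pcx and the pyruvate dehydrogenase subunit Pdha1 (-0.51 and -0.50), and none rose (camera adjusted p = 0.97, with a direction opposite in sign to the median of -0.02). None of 18 fatty acid oxidation genes passed (camera adjusted p = 0.24, with 11 of 18 estimates above 0). Of 16 biogenesis and mtDNA maintenance genes, Nrf1 rose (0.57 ± 0.11) and Sirt1 fell (-0.95 ± 0.25), the median was 0.02 and the mean -0.02, and the list was not called (camera adjusted p = 0.84). Tfam, which packages mtDNA, changed by 0.22 ± 0.10 (adjusted p = 0.17), and by 0.43 with GC offsets (adjusted p = 0.028), and Ppargc1a, a coactivator of biogenesis, by -0.93 ± 0.55 (adjusted p = 0.29). Of 19 dynamics and mitophagy genes, Sqstm1 and Bnip3 rose and the fission GTPase Dnm1l fell (camera adjusted p = 0.56). Of 12 mitochondrial chaperones and proteases, the proteases Afg3l2 and Lonp1 and the chaperone Dnaja3 rose and none fell (camera adjusted p = 0.56). With 1 library left out, Lonp1, Dnaja3, Sirt1, Bnip3, Dnm1l and Uqcrh each failed to pass in 4 of 6 fits, Nrf1, Sqstm1, Pcx and Pdha1 in 3, and Afg3l2 and Ndufv3 in 2. Lonp1 failed to pass in 21 of all 29 alternatives, GC offsets among them (adjusted p = 0.091, edgeR).

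Cholesterol biosynthesis genes fell together. Of 20 tested, 14 fell and none rose (18 fell adjusted over the list alone), with a median log2 fold change of -0.86 (camera adjusted p = 1.1e-09; adjusted p = 0.40 with an estimated correlation). The sterol oxidase Msmo1 changed by -1.49 ± 0.14 (SE), Cyp51 by -1.71 ± 0.16 and the sterol sensor Insig1 by -1.55 ± 0.16 (edgeR adjusted p = 0.0031 for each). Cell cycle genes fell too: 14 of 25 fell and none rose (17 fell and 1 rose adjusted over the list alone), with a median of -0.60 (camera adjusted p = 2.2e-06; adjusted p = 0.40 with an estimated correlation). The proliferation marker Mki67 changed by -2.03 ± 0.23 (adjusted p = 0.0038, edgeR), the kinetochore protein Cenpf by -2.85 ± 0.34 (adjusted p = 0.0042) and cyclin Ccnb1 by -1.10 ± 0.18 (adjusted p = 0.0093). Cell cycle members that fell numbered 2 without vehicle replicate 2, 2 without vehicle replicate 3, 9 without mitochondria replicate 2 and 9 without mitochondria replicate 3.

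Stress lists shifted upward by smaller amounts. Of 17 integrated stress response genes, 4 rose and none fell (4 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.016; adjusted p = 0.60 with an estimated correlation). They were Nupr1 (0.69 ± 0.10), Ddit4 (0.65 ± 0.10), Trib3 (0.66 ± 0.10) and the transcription factor Atf4 (0.55 ± 0.09). The list was not called with GC offsets (camera adjusted p = 0.10) or without vehicle replicate 2 (0.053), and 2 members passed without vehicle replicate 2 or 3. Of 15 ER chaperones, Sdf2l1 and Manf rose (6 rose adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.0095; adjusted p = 0.45 with an estimated correlation), and no member passed without vehicle replicate 2 or 3. None of the 20 autophagy and lysosome genes passed, although the list was called with a median of 0.14 (camera adjusted p = 0.049; adjusted p = 0.62 with an estimated correlation). That median was -0.02 under 1 scaling of the FPKM values, and the call was lost with GC offsets (camera adjusted p = 0.27), without vehicle replicate 2 (0.13), without vehicle replicate 3 (0.076), without mitochondria replicate 1 (0.10) and with the replicate number added to the model as a block (0.052).

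Cartilage genes, the matrix of the tissue, moved in both directions. Of 32 cartilage matrix and identity genes, 3 rose and 5 fell (5 and 5 adjusted over the list alone), and the list was not called (median -0.06, camera adjusted p = 0.78). The proteoglycan core protein Acan rose from 15 ± 1.97 to 21.8 ± 2.60 CPM (log2 0.54 ± 0.15, adjusted p = 0.041, edgeR), with an adjusted p of 0.060 with GC offsets. The chondrocyte transcription factor Sox9 rose by 0.54 ± 0.13 (adjusted p = 0.028). The fibrillar collagen Col2a1 changed by -0.16 ± 0.11 (adjusted p = 0.37) and by -0.38 with GC offsets (adjusted p = 0.0082). Prelp (-0.72 ± 0.10), Col11a1 (-0.94 ± 0.15), the link protein Hapln1 (-1.03 ± 0.17) and Sox6 (-1.02 ± 0.18) fell. The call of Acan was lost without any 1 of the 6 libraries, and that of Sox9 without vehicle replicate 2 or 3 and without mitochondria replicate 2 or 3. Hapln1 and Sox6 did not pass without vehicle replicate 2 or 3, and Hapln1 changed by -0.46 with GC offsets (adjusted p = 0.047, edgeR).

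Enzymes that degrade cartilage also split. Of 20, 5 rose and 5 fell (7 and 5 adjusted over the list alone), and the list was not called (median 0.00, mean 0.13, camera adjusted p = 0.66). With 1 library left out, 3 to 6 of them rose and 2 to 6 fell. Stromelysin Mmp3 (chromosome 9, 7445822 to 7455975) rose from 10512 ± 1225 to 17479 ± 1126 CPM (SD, n = 3; log2 0.73 ± 0.09, adjusted p = 0.0047, edgeR) and gelatinase Mmp9 rose by 1.64 ± 0.16 (adjusted p = 0.0031). In limma fits to FPKM, the call of Mmp3 was lost with quantile normalization (log2 0.25, adjusted p = 0.11) and with no filter on FPKM (log2 0.67, adjusted p = 0.23). The aggrecanase Adamts5 (chromosome 16, 85856173 to 85901828) fell from 101 ± 27.6 to 28.9 ± 3.15 CPM (log2 -1.80 ± 0.20, adjusted p = 0.0037), and the hyaluronan-degrading protein Cemip fell as well (-1.63 ± 0.18, adjusted p = 0.0035). Collagenase Mmp13 changed by 0.12 ± 0.16 (adjusted p = 0.67), and by 0.53 with GC offsets (adjusted p = 0.0064).

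Targets of IL-1 and NF-kB were mixed. Of 35, 8 rose and 3 fell (9 and 6 adjusted over the list alone), and the list was not called (median 0.16, camera adjusted p = 0.28), though it was with GC offsets (median 0.22, camera adjusted p = 0.032; adjusted p = 0.63 with an estimated correlation) and without vehicle replicate 1 (0.024). Members that rose numbered 2 without vehicle replicate 2, 2 without vehicle replicate 3 and 13 without vehicle replicate 1. The chemokine Ccl5 rose by 1.83 ± 0.13 (SE; adjusted p = 0.0020, edgeR), prostaglandin E synthase Ptges by 1.25 ± 0.21 (adjusted p = 0.0094) and the acute-phase protein Saa3 by 0.48 ± 0.08 (adjusted p = 0.0099), while the metalloreductase Steap4 fell (-0.75 ± 0.11, adjusted p = 0.0062). Inducible nitric oxide synthase Nos2 rose from 830 ± 232 to 1666 ± 166 CPM (adjusted p = 0.011), a call lost, as were those of Ptges and Saa3, without vehicle replicate 2 or 3. The cytokine Il6 changed by -0.23 ± 0.18 (adjusted p = 0.44), and by 0.35 with GC offsets (adjusted p = 0.019), the opposite direction. Cyclooxygenase Ptgs2 changed by 0.32 ± 0.24 (adjusted p = 0.39), and by 0.86 with GC offsets (adjusted p = 0.017).

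Hypertrophy and mineralisation genes were not called as a list (13 tested, 2 higher, 1 lower, median -0.17, camera adjusted p = 0.40). Phospho1 rose by 0.98 ± 0.16 and Vegfa by 0.61 ± 0.13, while Ibsp fell (-2.31 ± 0.52), and the hypertrophic collagen Col10a1 changed by -0.01 ± 0.19 (adjusted p = 0.98, edgeR). With 1 library left out, Ibsp failed to pass in 4 of 6 fits, Vegfa in 2 and Phospho1 in 1, and no member of the list passed without vehicle replicate 2. Of 14 fibroblastic dedifferentiation genes, 5 fell and none rose (6 fell and 1 rose adjusted over the list alone), and the list was not called (median -0.20, camera adjusted p = 0.056; adjusted p = 0.45 with an estimated correlation). It was called in 20 of 28 refits, among them the fits with GC offsets (0.0046; 0.32 with an estimated correlation), without vehicle replicate 2 (0.044) and without mitochondria replicate 1 (0.028). The contractile genes Acta2 (-1.94 ± 0.20, adjusted p = 0.0031) and Tagln (-1.47 ± 0.14, adjusted p = 0.0031) fell, as did the type I collagen chain Col1a2 (-0.46 ± 0.09, adjusted p = 0.015), whose call was lost in 3 of the 6 fits with 1 library left out. In the TGF-beta and BMP list, 4 of 20 rose and 5 fell (camera adjusted p = 0.62), with Tgfb2 (-1.27 ± 0.16) and Ltbp1 (-0.50 ± 0.08) among those that fell and Ccn2 (0.48 ± 0.08) and Id1 (0.59 ± 0.10) among those that rose. Without vehicle replicate 2, and likewise without vehicle replicate 3, none of this list rose and 1 fell, and Ltbp1, Ccn2 and Id1 each failed to pass in 2 of the 6 fits with 1 library left out. In the apoptosis list, Fas, Bid and Xiap fell and Diablo rose (18 tested, camera adjusted p = 0.62). With GC offsets Fas and Xiap did not pass (adjusted p = 0.13 and 0.076, edgeR), and with 1 library left out Xiap and Diablo each failed to pass in 4 of 6 fits, Bid in 3 and Fas in 2. In the senescence and p53 list, Glb1 was among the genes that rose, and Ccng1 and Lmnb1 were among 3 that fell (15 tested, median 0.19, mean -0.04, camera adjusted p = 0.49). Glb1 and Lmnb1 each failed to pass in 5 of the 6 fits with 1 library left out and Ccng1 in 3, and Glb1 had an adjusted p of 0.059 with GC offsets (edgeR).

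Markers of other cell types moved with the groups as follows. Erythroid markers fell in 4 of 7 genes tested (5 adjusted over the list alone), with a median of -0.74 (camera adjusted p = 0.0035; adjusted p = 0.45 with an estimated correlation), and the beta-globin Hbb-bs was at 57.0 ± 6.26 CPM with vehicle and 30.6 ± 1.89 CPM with mitochondria (SD, n = 3). Without vehicle replicate 3, mitochondria replicate 2 or mitochondria replicate 3, 2 erythroid markers passed. Synovial fibroblast markers fell in 5 of 11 genes and rose in 1 (7 and 1 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 0.034; adjusted p = 0.40 with an estimated correlation), Dpp4 (-1.88 ± 0.28) and Pdgfra (-0.64 ± 0.11) among them, and their call was lost without vehicle replicate 1 (0.052), without vehicle replicate 2 (0.054), without mitochondria replicate 2 (0.059) and with the replicate block (0.052). Without vehicle replicate 2 or 3, 1 synovial marker fell and none rose. Adipocyte markers fell in 2 of 9 genes, Lpl and Adipoq, with a median of -0.50 (camera adjusted p = 0.049; adjusted p = 0.40 with an estimated correlation), a call lost without vehicle replicate 1 (0.13), without vehicle replicate 2 (0.054), without mitochondria replicate 2 (0.11) and with the replicate block (0.068). Pdgfra, Lpl and Adipoq each failed to pass in 2 of the 6 fits with 1 library left out. The adipocyte list was called in 10 of 27 refits and in 1 of 6 rescalings, with medians from -0.71 to -0.12. None of 9 endothelial markers passed (median 0.86, camera adjusted p = 0.065), and the list was called without vehicle replicate 3 (0.029) and without mitochondria replicate 3 (0.041). Among them Flt1 (0.91, adjusted p = 0.051, edgeR) passed in 6 of 18 alternatives, GC offsets (0.043) and the fit without vehicle replicate 1 (0.011) among them. Skeletal muscle markers (9 tested, Myh8 lower, camera adjusted p = 0.12) and osteoclast markers (5 tested, Mmp9 higher and Ctsk lower, camera adjusted p = 0.56) were not called, and with 1 library left out Ctsk failed to pass in 5 of 6 fits and Myh8 in 4. Of 9 osteocyte markers tested, Tnfsf11 fell (-0.93 ± 0.15, adjusted p = 0.0083, edgeR) and none rose (camera adjusted p = 0.96), and the osteocyte genes Dmp1, Sost and Phex were under the count filter.

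**Figure D3:**
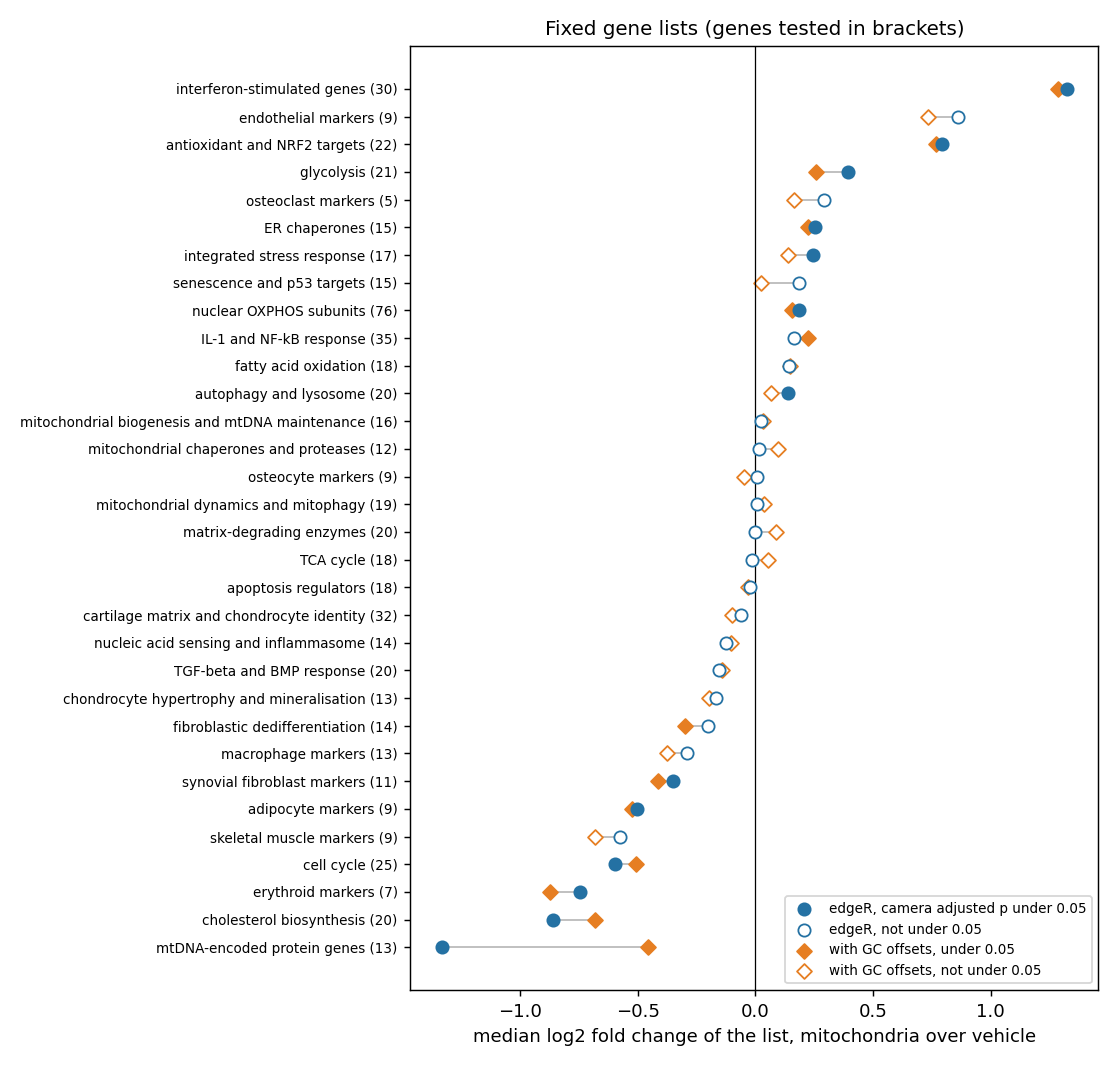
Median log2 fold change (mitochondria over vehicle) of each fixed list, with the genes tested in brackets, as circles for the edgeR fit and diamonds for the fit with GC offsets; filled symbols have a camera adjusted p under 0.05. Interferon-stimulated genes lie at 1.33 and mtDNA-encoded genes at -1.33 without GC offsets, and at 1.29 and -0.46 with them.

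In all, 13 of the 32 lists were called by camera with its preset correlation, 7 upward and 6 downward, and none with an estimated correlation, where the smallest adjusted p was 0.059. The synovial and adipocyte lists lost their calls there with estimated correlations of -0.024 and -0.081, below the preset. That test has few degrees of freedom here and cannot tell whether correlation removes the calls. Fry called 17 lists for a shift in 1 direction and 31 for changes in either direction. With GC offsets 13 lists were called, 11 of them among the 13 above, and none with an estimated correlation (smallest adjusted p = 0.16). Under the 6 rescalings the median ranged from 0.01 to 0.18 for nuclear OXPHOS subunits, from 0.08 to 0.24 for the integrated stress response and from 0.09 to 0.25 for ER chaperones.

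The largest changes by the rule lay at very low levels. Among genes at 0 in all vehicle libraries, Shbg was at least 8.56-fold higher with mitochondria, Grap at least 6.47-fold, Tekt5 at least 6.29-fold and Pcp4 at least 4.54-fold, and Cfap299 and Spata17 were each at least 3.58-fold higher. Among genes at 0 in all mitochondria libraries, Usp50 was at least 19.95-fold lower, Chodl at least 12.24-fold, Prokr2 at least 10.33-fold, Sla at least 7.23-fold, and Scel, Rgs7bp, Agtr1b and Asb2 at least 4.45-, 4.29-, 4.21- and 2.78-fold. These folds leave out the counting error of the expressed group, which held 35 deposited counts for Asb2. Of these 14 genes, Usp50 alone was still tested once counts had been divided by 4. Usp50 also passed in all 6 fits with 1 library left out, whereas Cfap299, Spata17 and Asb2 passed in none of them, Rgs7bp failed to pass in 5, Grap, Pcp4, Scel and Agtr1b in 4, Tekt5 in 3, and Shbg, Chodl, Prokr2 and Sla in 2. The cytokine Il1b rose from 0.351 ± 0.486 to 7.57 ± 1.46 CPM (log2 4.43 ± 0.91, adjusted p = 0.017, edgeR), a call lost without vehicle replicate 2, and the interferon-induced genes Mx2 and Apol9b by 3.79 ± 0.53 and 3.76 ± 0.61 (adjusted p = 0.0056 and 0.0083). The vehicle values of Il1b were 0.906, 0.149 and 0 CPM, and its log2 change ranged from 3.841 to 6.625 with 1 library left out. Pax5 rose (4.74 ± 1.18, adjusted p = 0.031), and Tceal5 and Ms4a7 fell (-4.59 and -4.58, adjusted p = 0.040 and 0.041), all 3 below 1 CPM in both groups. With 1 library left out the calls of Pax5, Tceal5 and Ms4a7 were lost in 4, 5 and 5 of 6 fits, and the fitted log2 changes reached 8.26, -7.28 and -8.17.

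Among genes at 10 CPM or more, a selection made after the values had been seen, the largest increases after Isg15 were in the aldehyde dehydrogenase Aldh3a1 (2.82 ± 0.25), Irf7, the placental growth factor Pgf (2.27 ± 0.47), Trdc (from 7.55 to 30.3 CPM), stromelysin-2 Mmp10 (1.87 ± 0.30), Nqo1, Ccl5, the antiviral protein Bst2 (1.81 ± 0.17) and uridine phosphorylase Upp1 (1.74 ± 0.34). The largest decreases were in the imprinted gene Mest (-3.96 ± 0.45), from 240 ± 122 to 15.5 ± 5.01 CPM, the small leucine-rich proteoglycans Ogn (-3.50 ± 0.45) and Aspn (-2.50 ± 0.33), the growth factor Igf1 (-2.98 ± 0.32), Nhs (-2.76 ± 0.35), the peptidases Mme (-2.66 ± 0.48) and Enpep (-2.44 ± 0.27), Ndnf (-2.66 ± 0.38), Phip (-2.63 ± 0.34) and Limch1 (-2.47 ± 0.25). With GC offsets Ogn changed by -2.69, Igf1 by -2.22, Mme by -2.04, Phip by -2.02 and Aspn by -1.56. The edgeR adjusted p of these 20 genes ranged from 0.0020 to 0.017, and Pgf, Trdc, Upp1 and Mme did not pass without vehicle replicate 2 or 3. Vehicle replicate 1 was the highest of its group for Pgf (10.5, 2.65 and 3.08 CPM in vehicle replicates 1, 2 and 3) and Trdc (13.4, 4.98 and 4.25 CPM). With 1 library left out their log2 changes ranged from 1.938 to 3.179 and from 1.717 to 2.71.

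Fold changes followed the GC content of the genes (Spearman rho 0.479 across 12345 genes, which are not independent replicates). They fell with transcript length (rho -0.377 across the same genes). In the 1236 genes of lowest GC content (33.15% to 41.94%), the median log2 fold change was -0.53, and 412 genes fell while 19 rose. The slope of expression on GC content, in log2 units per 10 points, was -0.155, -0.204 and -0.172 in the vehicle libraries and 0.469, 0.0016 and 0.060 in the mitochondria libraries. The group means differed by 0.354 (exact two-sided permutation p = 0.10, the smallest this design allows), and mitochondria replicate 1 stood apart from the other libraries of its group. Without it the difference was 0.208.

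**Figure D4:**
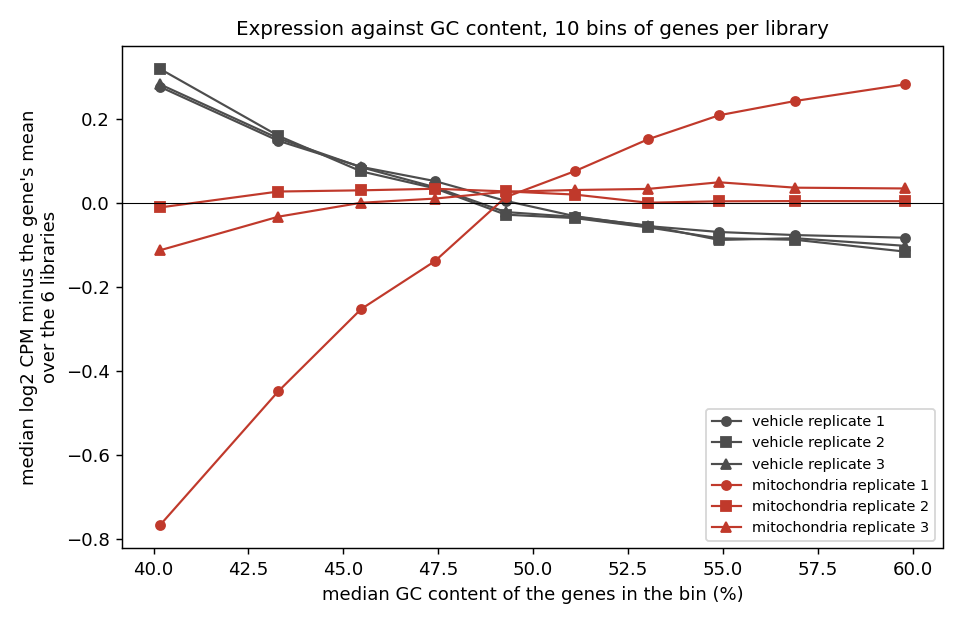
Median log2 CPM relative to each gene's mean over the 6 libraries (vertical axis) against the median GC content in percent of 10 bins of genes (horizontal axis), 1 line per library. The 3 vehicle lines fall with GC content, and mitochondria replicate 1 rises from -0.77 in the lowest bin.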

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

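The tests with GC offsets, GC and length offsets, counts divided by 4, limma at its planned settings and TMM without mtDNA-encoded genes, and the share of mtDNA-encoded transcripts in counts, were chosen after seeing the data; the other alternatives were fixed before the data were examined. The number of genes higher with mitochondria (1099) ranged from 130 to 1086 with 1 library left out, and the number lower (1463) from 310 to 1694. Without a count filter edgeR called 357 higher and 507 lower, and limma without an FPKM filter 161 and 301, with 26044 and 26043 genes tested. At a mean FPKM of at least 5 limma called 709 and 782 of 6605 genes, and a minimum fold of 2 left 237 and 704. Limma on TPM called 728 higher, limma on FPKM rescaled without mtDNA-encoded genes 605, and GC and length offsets 1655; the share of called genes that were higher was 42.9% in the edgeR fit reported, and 29.63%, 22.94% and 53.79% in these. Limma on FPKM without rescaling called 914 higher and 1568 lower (36.83% higher). Against the edgeR fit the median of all genes moved by -0.0691 in limma without rescaling. The move was -0.118 with TPM and -0.163 without mtDNA-encoded genes. It was -0.00608 in limma with median-of-ratios scaling and -0.000871 with quantile normalization. In the limma fits these moves therefore followed the scaling of the libraries. For other moved counts the cause was not tested. DESeq2 called 1514 higher and 2193 lower, and the replicate block 898 and 1386. No gene called higher was called lower in any alternative, and 4 called lower were called higher with GC and length offsets. Of 13 lists called, 0 were called with an estimated correlation, and 9 to 14 in the refits; 6 lists were called in all 28 of them: mtDNA-encoded genes, glycolysis, NRF2 targets, interferon-stimulated genes, cholesterol biosynthesis and erythroid markers. Over all lists, 838 of 945 values stayed on their side of the threshold, 71 lost and 35 gained a call, and 1 had the opposite direction with a call: hypertrophy and mineralisation at a mean FPKM of at least 5 (median 0.5525, fewer genes tested). Among the 838, the direction of the test changed in 56 values of 11 lists, with no call in either fit, and the median changed sign in 87 values of 13 lists. Of 4514 values for 172 named genes, 3883 stayed on their side, 506 lost and 122 gained a call, and 3 had the opposite sign with a call, all of Il6: 0.354 with GC offsets, 0.3592 also without mitochondria replicate 1, and 0.3598 also with the replicate block. Among the 3883, 10 values changed sign with no call in either fit, of Mmp13, Il6, Col10a1 and Gabpa. Of 127 named genes called, 75 lost the call without vehicle replicate 2, 74 without vehicle replicate 3 and 40 without mitochondria replicate 3. The difference in the share of mtDNA-encoded transcripts, -2.91 points of FPKM, ranged from -3.284 to -2.475 with 1 library left out, and was -0.9132 points of deposited counts and -0.3622 after GC offsets. Of the 2562 changed genes, 46 fell below the minimum count of 10 after counts were divided by 4, and 10 were at 0 in all vehicle and 16 in all mitochondria libraries, where depth allows only a lower bound on the fold. DESeq2 gave no value for the lists.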

Other observations

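The tests of the groups in this paragraph and the next, of GC bias, of GC and length offsets, of macrophage markers and of nuclear genes nearest in GC content, in lists or 1 by 1, were chosen only after results had been seen; the splits of the samples, the matched nuclear lists, the single libraries and the sterol test were written before their results were seen. Among pathways of KEGG, 19 of 306 were called by camera and none with an estimated correlation (smallest adjusted p = 0.70). Ribosomal genes shifted upward as a group, with 11 of 132 higher, none lower and a median log2 fold change of 0.19 (camera adjusted p = 8.5e-07; adjusted p = 0.72 with an estimated correlation). With GC offsets 19 were higher and the median was 0.14. Fold changes over all genes fell with transcript length (Spearman rho -0.377), and pathways were not tested with length offsets, so a length trend may underlie this shift. Antigen processing and presentation held 15 higher genes of 57 and none lower, and the class I heavy chains H2-K1 and H2-D1 rose by 0.83 ± 0.13 and 0.78 ± 0.12 (SE; edgeR adjusted p = 0.0082 and 0.0067). They were the 2 that passed among 10 class I presentation genes looked up after the values had been seen. B2m, Tap1, Tap2, Tapbp, Psmb8, Psmb9, Psmb10 and Nlrc5 did not pass, and Psmb10 had an estimate of -0.42. With GC offsets B2m rose by 0.64 (adjusted p = 0.00086) and Psmb10 fell (-0.59, adjusted p = 0.044). The pentose phosphate pathway, a source of NADPH, held 9 higher genes of 26 and none lower, among them Pgd (0.86 ± 0.12) and Taldo1 (0.79 ± 0.13), and 8 of 43 proteasome genes rose and 1 fell. The higher pentose phosphate genes also included Gpi1, Pgm1 and Pfkp, which KEGG counts under glycolysis too, so the call of the pathway overlaps that of glycolysis. Pgd, Taldo1 and G6pdx (0.49 ± 0.09, edgeR adjusted p = 0.013), which KEGG does not count under glycolysis, rose as well. With GC offsets 8 pentose phosphate genes rose and 1 fell, and 16 proteasome genes rose and 2 fell. Of 7 genes of this pathway and of NADPH supply looked up after the values had been seen, 3 rose and the NADPH-producing Idh1 fell (-0.76 ± 0.18, edgeR adjusted p = 0.028; 0.088 with GC offsets). The cytosolic DNA-sensing pathway was called upward, with 11 of 46 genes higher and 1 lower (camera adjusted p = 0.024; 0.011 with GC offsets and 0.70 with an estimated correlation), although the fixed list of nucleic acid sensors was not. Its higher genes included Irf7 of the interferon list, Ccl5 of the IL-1 and NF-kB list, Il1b, Adar, Zbp1 and Ddx58. The call therefore overlaps, in part, changes described above and does not by itself show DNA sensing. The KEGG cell cycle was not called, with 5 of 119 genes higher and 24 lower (camera adjusted p = 0.15; 0.34 with GC offsets), whereas the fixed list of 25 was.

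Several genes that fell had been noticed as groups only in these values. Of 14 imprinted genes that act in growth, 7 fell and 1 rose: Mest, Plagl1 (-1.70 ± 0.31), Cdkn1c (-1.38 ± 0.20), Peg3 (-1.16 ± 0.21), H19 (-0.97 ± 0.14), Meg3 and Grb10 fell, and Dlk1 rose (0.51 ± 0.12). Of 8 smooth-muscle contractile genes, 5 fell, with Actg2 (-1.98 ± 0.21), Cnn1 (-1.74 ± 0.26) and Myl9 (-1.48 ± 0.18) beside Acta2 and Tagln. Of the neighbouring genes Ogn, Omd, Aspn and Ecm2, 3 fell, and Ecm2 changed by -0.78 ± 0.31 (edgeR adjusted p = 0.13). No enrichment test was run on these groups. Of 5 sex-linked genes looked up in the same way, 2 fell. The X-inactivation transcript Xist went from 521 ± 26.6 to 171 ± 104 CPM (SD, n = 3; edgeR adjusted p = 0.030) and the Y-linked Ddx3y from 22.6 ± 3.30 to 8.29 ± 3.30 CPM (adjusted p = 0.016), and both were present in each of the 6 libraries. Their log2 changes of -1.61 and -1.44 were -1.26 and -0.64 with GC offsets (adjusted p = 0.013 and 0.015).

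The 6 samples can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. In 1 of these splits, the real one, the number of changed genes was as large as 2562, and the highest of the other splits gave 1 gene. For the fixed lists, 1 split gave as many as the 13 called, again the real one, and the highest other split gave 10.

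For the lower mtDNA-encoded transcripts, part of the change remained with offsets for the GC content and length bias of the libraries. The median was -0.48 with them (11 of 13 members called), against -1.33 without. The offsets had to be extended to members of lower GC content (down to 31.86%) than the nuclear genes they were trained on. Such bias is therefore not excluded as the whole change. Without mitochondria replicate 1 alone, 12 members were still called. Of 10000 random nuclear lists matched in windows of GC content and expression 0.07% had a median as low, which met the bound written beforehand, and of lists drawn from the 50 nuclear genes nearest in GC content, added because 1 window held a single gene, 0% did. The genes drawn were richer in GC, with medians of 41.22% and 40.01% against 37.12% for the members. Genes of higher GC content fell less here, so these shares and the single-gene share below may understate how far matched genes fell. Whether nuclear genes of like GC content fall as far is read as open, a change made after the values had been seen: the 13 members move as a unit (estimated correlation 0.961), as separately drawn genes do not, and with the list taken as a single gene 6.46% of the nearest nuclear genes had a fold change as low. Part or all of the change may be GC bias, and a lower share of mitochondrial RNA in the treated cells remains a hypothesis, since neither mtDNA copies nor the origin of the transcripts was measured.

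The higher interferon-stimulated genes were set against 3 technical explanations. If macrophages alone carried both the markers and the interferon-stimulated genes, more of them would raise the markers by about the list's median of 1.33. The log2 ratio of the markers' summed level was -0.0332 ± 0.128 (SE). Cd14 (24.2 and 32.7 CPM with vehicle and mitochondria) and Lyz2 (39.9 and 30.0 CPM) made up most of that sum and moved in opposite directions. The sum therefore cannot exclude more macrophages, and it does not bear on their activation. GC content and length bias of the libraries left the median at 1.29 with offsets. A single library did not carry the call, since the highest camera adjusted p with 1 of the 6 left out was 1.3e-10. An interferon response of the chondrocytes to the mitochondria or to something prepared with them is a candidate explanation, and a preparation without mitochondria, which would separate these, was not used here.

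The lower level of AT-rich genes cannot be told apart from GC content bias that differs between libraries, since any such bias would go with the groups here. The slopes within the mitochondria group spanned 0.467 log2 units per 10 points of GC, more than the difference of 0.354 between the group means. That span rests on mitochondria replicate 1: without it the slopes spanned 0.0584 and the group means differed by 0.208. Whether the slope arose in the cells or in library preparation could not be settled with 3 libraries per group.

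For the lower cholesterol biosynthesis genes, sterol excess in the treated cells was tried as a hypothesis through 6 genes induced by oxysterols and LXR. Their median log2 fold change was -0.27 with an SD of 0.64, and they went both ways: Abca1 fell (-0.98 ± 0.13) and Abcg1 rose (0.82 ± 0.18). The bound written beforehand against sterol excess (a median of 0 or lower with at most 1 member higher) was met, but by less than the spread of the members, and the reading was changed from an exclusion to an open one for that reason after the values had been seen. Sterol excess may therefore still apply.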
